A study of Pimephales promelas with 30 samples.

How the data were processed

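Gene expression was measured in liver and whole blood of reproductively mature male fathead minnow (Pimephales promelas), a small freshwater fish used in ecotoxicology, after a 48 h exposure through the water. Per the labels, the exposures were a vehicle control, perfluorooctane sulfonate (PFOS) at 0.5 µg/L (low PFOS) or 25 µg/L (high PFOS), and a mixture of 7 perfluorinated chemicals. The labels describe 4 aquaria per exposure with 2 fish in each. Liver and blood came from the same fish, but the labels do not tie a liver array to a blood array, nor an array to an aquarium, so no term for fish or aquarium could be fitted. Where arrays share an aquarium, p-values that treat them as independent are too small. The 30 arrays made 8 groups, with 3 arrays each in liver control and blood high PFOS and 4 in every other group.

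Per the labels' protocols, 25 ng of blood RNA or 50 ng of liver RNA was labelled with Cy3 and hybridized to a custom 1-colour Agilent array with 60-base probes, and RNA integrity numbers ranged in blood from 8.1 up to 9.3 and in liver from 7.5 up to 9.4. RNA input therefore cannot be told apart from tissue. The deposited scanner files hold spot intensity values on a linear scale, background-subtracted and spatially detrended by Agilent Feature Extraction per the file headers; the submitters' processing notes give version 9.5 and the headers version 10.1.1.1. Feature Extraction treats each array by itself, so these values were not yet comparable between arrays. A table of log2 values deposited by the authors covers 15203 of the 15208 probes. Its method, scale factor and centring are not given in the sources used here, and with 1 colour it has no direction to settle. The medians of its columns lay between 5.92 and 6.02 for liver and between 6.33 and 6.84 for blood, the highest being low PFOS array 2, so the tissues were treated as normalized apart and the table was used only within a tissue, as an alternative.

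Each column of that table was set against the log2 scanner signals of all arrays. In 27 of 30 columns the best match was the array of the same sample, with r of at least 0.996. The column of blood low PFOS array 2 had r = 0.938 with its own scanner file, though all of its 1254 empty cells were spots flagged in that file. The column of blood mixture array 4 matched the scanner file of blood control array 2 (r = 0.996), and all of its 108 empty cells were spots flagged in that file, against r = 0.94 with its own scanner file. The column of blood control array 2 had its highest r, 0.959, with the scanner file of another sample. Scanner files were kept with the sample they are recorded for, and each blood count was recomputed with the identities of the value table.

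The array carried 15744 spots, of which 536 were controls and were left out. Log2 of the processed signal minus the 75th percentile of each array was used, spots flagged as non-uniform or population outliers were set to missing, and saturated spots were kept. A probe was tested in a tissue if it was well above background on at least 3 arrays of that tissue and had at least 2 unflagged values in every group, which left 12955 probes in liver and 12895 in blood. Fits of both tissues used 13855 probes well above background on at least 3 arrays of either tissue. The 4 groups of a tissue were fitted together with limma 3.58.1 in R 4.3.3, without covariates, with moderated variances, two-sided tests and Benjamini-Hochberg adjustment at 0.05 over the probes of a comparison. The 3 tissue differences, (blood exposed minus blood control) minus (liver exposed minus liver control), and the comparison of the control tissues used all 30 arrays. The number of arrays per group limits the precision.

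The fitting code gave the p-values of limma on the real values, and it was tested on simulated arrays with the means and variances of the real ones, in which 200 probes were changed by a known fold. Of these, 55.5% changed 4-fold and 83% changed 8-fold were recovered for liver low PFOS against control among 12955 probes, and 20% and 67.5% for blood high PFOS against control among 12895 probes. No probe changed 2-fold was recovered in either. For the tissue difference in the high PFOS effect, 8% of the 4-fold and 50% of the 8-fold changes were recovered among 13855 probes.

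No probe could be given a gene name. The description of every probe reads as unknown, and 0 of the probe or contig names occurred in the reference table of 64593 genes. The gene lists and cell type markers fixed before the data were examined could therefore not be tested, and probes are reported by probe ID, contig ID and sequence. The rule for named genes was replaced after it was known that no names existed and after test results had been seen: for each comparison at most 2 probes that were higher and 2 that were lower are named, first those past the threshold with the largest change, and for the 6 comparisons of an exposure with control then those with the smallest p among probes whose exposed and control arrays did not overlap, which are said not to have passed. Probes that the rule picked but that are not reported here were not replaced by others. Where a probe was not well above background on any array of the dimmer group, the change is given as "at least N-fold", the mean of the brighter group against the mean over the dimmer arrays of the higher of the probe's own value and the lowest value well above background on that array.

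The 4 slides, each scanned as 1 batch, all held several groups and both tissues. No probe differed between slides past the threshold in limma within groups, with 867 of 12955 in liver and 667 of 12895 in blood at an unadjusted p under 0.05. Blood arrays carry the numbers 1 to 4 in every group (1 to 3 in high PFOS). Deviations from the group means correlated over 0.1 in 6 of 21 pairs with the same number, so the numbers were not taken to pair the arrays. No 2 arrays of a group held identical values. Alternatives planned before the data were examined were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, the value table, no filter, a filter requiring every array to be well above background, slide as a fixed or random block, leaving out each array, only the 2 groups compared, all 30 arrays, and the replicate number as a block in blood. Array weights, leaving out 3 doubted blood arrays, the identities of the value table, and a contrast of all exposures with control in liver were added after seeing the data.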

Results

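The series profiled liver and whole blood of male fathead minnow to set the response of a tissue that is simple to sample beside that of the liver, after exposure to PFOS at 2 concentrations or to a mixture of perfluorinated chemicals. The 15 liver arrays had 60.7% to 82.8% of probes well above background, and their 75th percentile signals ran from 268 to 618 intensity units. The 15 blood arrays ran from 60.4% to 82.2% well above background, apart from low PFOS array 2 with 95.1%, and from 513 to 1251 intensity units at the 75th percentile. Each liver array had a Spearman correlation of at least 0.945 with the median liver profile. Blood arrays had at least 0.944 with the median blood profile, apart from low PFOS array 2 with 0.792. Residual spread between fish of a group had a median SD of 0.60 log2 units in liver and 0.76 in blood.

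Of 15208 probes, 8215 were well above background on all 15 liver arrays, 6409 on all 15 blood arrays and 5175 on all 30. The control tissues were compared first, since the size of the tissue difference sets the scale for the exposures. In limma, 6731 of 13855 probes differed between liver and blood controls, with 3789 higher in liver and 2942 higher in blood. Probe UF_Ppr_AF_116118 (contig FJU.192.C2___1_nrnt, sequence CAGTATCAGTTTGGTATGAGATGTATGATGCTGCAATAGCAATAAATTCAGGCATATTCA) was saturated on all 3 liver control arrays and not well above background on any of the 4 blood control arrays, at least 9813-fold higher in liver (adjusted p = 6.73e-14). Probe UF_Ppr_AF_102144 (contig FJU.244.C1___1_nrnt, sequence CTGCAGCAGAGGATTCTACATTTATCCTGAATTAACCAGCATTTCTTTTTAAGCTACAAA) was at least 7215-fold higher in liver (adjusted p = 8.62e-18).

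On the blood side, probe UF_Ppr_AF_104985 (contig gi_73450751___1_nrnt, sequence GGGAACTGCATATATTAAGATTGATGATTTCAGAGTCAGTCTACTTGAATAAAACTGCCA) stood at 5.67 ± 0.83 (SD, n = 4) in blood control and -1.36 ± 0.41 (SD, n = 3) in liver control, in log2 units relative to the 75th percentile of the array. The log2 difference, liver minus blood, was -7.03 ± 0.57 (SE, limma adjusted p = 2.54e-10). Since 2 of the 4 blood control arrays were saturated, it may understate the size. Under the alternatives it ran from -7.561 to -6.725. Probe UF_Ppr_AF_118877 (contig FJU.9261.C1___1_nrnt, sequence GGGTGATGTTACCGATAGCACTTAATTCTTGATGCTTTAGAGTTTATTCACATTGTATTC) was at least 104-fold higher in blood than in liver, where none of the 3 control arrays was well above background (limma adjusted p = 0.000961), and at least 42.9-fold without blood control array 2. On both slides that held the 2 control groups these 4 probes kept their direction. Their control groups did not overlap, so this direction was fixed and is no support. Under the alternatives the log2 difference came down to 9.706 for UF_Ppr_AF_116118, 9.702 for UF_Ppr_AF_102144 and -4.088 for UF_Ppr_AF_118877. These are smaller than the bounds given, so those folds hold for the main setting alone. The median of all probes differed by 0.39 log2 units between tissues, so directions are relative to that shift, and RNA input differed with tissue. With probes restricted to those well above background on every array, 2812 differed, 1116 of them higher in liver and 1696 higher in blood, so the majority direction turned.

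Low PFOS against control asked whether 0.5 µg/L changed liver transcripts. No probe passed the threshold in liver (limma, 0 of 12955), and 960 had an unadjusted p under 0.05 where 648 are expected by chance. The smallest p belonged to probe UF_Ppr_AF_103929 (contig FJU.13523.C1___1_nrnt, sequence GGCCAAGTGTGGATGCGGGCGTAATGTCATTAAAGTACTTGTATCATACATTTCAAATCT), at 1.20 ± 0.40 (SD, n = 4) in low PFOS and -1.11 ± 0.33 (SD, n = 3) in control. The log2 difference was 2.31 ± 0.32 (SE), with all 4 exposed fish above all 3 controls, and the limma adjusted p was 0.0551. Within the 3 slides that held both groups it was 2.57, 2.17 and 2.28. Probes that did not pass were named only if exposed and control arrays did not overlap. This separation and the direction within slides are therefore no support. Over all probes 9.58% were separated in this way, in either direction, where 5.71% are expected by chance. Probe UF_Ppr_AF_114228 (contig FJU.4685.C2___1rc_nrnt) had a log2 difference of 1.60 ± 0.30 (SE; limma adjusted p = 0.211).

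Among probes with lower signal in liver at low PFOS, UF_Ppr_AF_103144 (contig FJU.3019.C1___1_nrnt, sequence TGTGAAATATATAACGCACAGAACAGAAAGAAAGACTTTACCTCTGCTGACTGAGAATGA) stood at 0.77 ± 0.58 (SD, n = 4) against 4.43 ± 0.81 (SD, n = 3) in control, a log2 difference of -3.66 ± 0.54 (SE; limma adjusted p = 0.0551). Probe UF_Ppr_AF_105283 (contig FJU.667.C1___1_nrnt, sequence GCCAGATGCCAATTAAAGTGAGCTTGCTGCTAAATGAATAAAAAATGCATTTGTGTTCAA) had -3.88 ± 0.61 (SE; limma adjusted p = 0.076) and was well above background on 1 of the 4 low PFOS arrays and on all 3 controls. The count is sensitive to the setting: normexp with quantile normalization gave 5 probes, the deposited log2 values gave 3 and all 30 arrays 7, while slide as a fixed block gave 0.

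**Figure D1:**
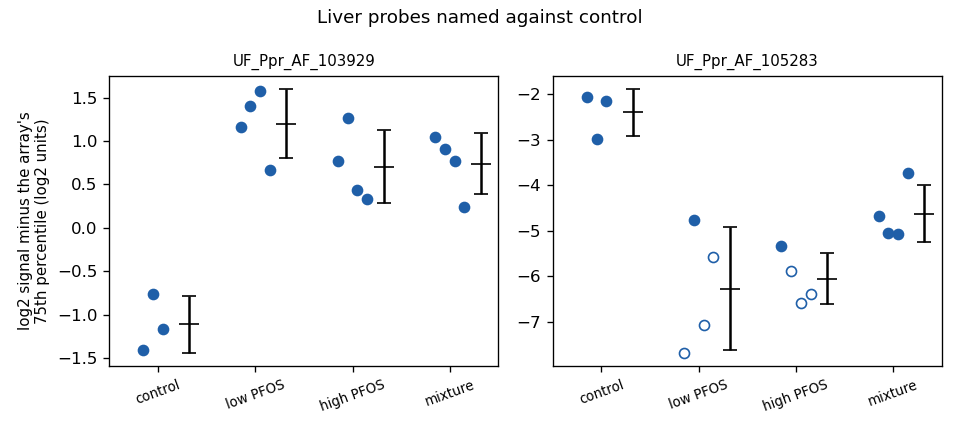
Log2 signal relative to the 75th percentile of the array (vertical axis, log2 units) of 2 liver probes in the 4 exposure groups (horizontal axis). Each point is 1 array, filled where the probe was well above background and open where it was not, and bars give the mean and SD. All exposed arrays lie above the 3 controls for UF_Ppr_AF_103929, and all lie below them for UF_Ppr_AF_105283. Separation from control was part of the rule by which both probes were named.

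High PFOS against control tested the same liver at 25 µg/L. Again no probe passed in limma (0 of 12955), with 892 at an unadjusted p under 0.05. UF_Ppr_AF_103929 had a log2 difference of 1.82 ± 0.32 (SE), UF_Ppr_AF_105283, well above background on 1 of 4 high PFOS arrays, had -3.66 ± 0.61 (SE), and UF_Ppr_AF_108050 (contig FJU.10377.C2___1_nr0nt1) had -2.45 ± 0.43 (SE), each with a limma adjusted p of 0.176. Slide 1 alone held both groups, and its differences were 2.43, -3.55 and -2.06 in that order. Normexp with quantile normalization and the fit of all 30 arrays each gave 2 probes past the threshold.

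The mixture against control gave 0 of 12955 liver probes in limma and 829 at an unadjusted p under 0.05. UF_Ppr_AF_103929 had a log2 difference of 1.85 ± 0.32 (SE), with a limma adjusted p of 0.511. It lay above all controls on every mixture array, which the rule for naming required. Over all probes 5.93% were separated from control in either direction, where 5.71% are expected by chance. UF_Ppr_AF_100743 (contig FJU.9039.C1___1_nrnt), well above background on 1 of 4 mixture arrays, had -3.14 ± 0.62 (SE; limma adjusted p = 0.511). UF_Ppr_AF_109691 (contig FJU.11222.C1___1_nrnt) was not well above background on any mixture array and was at least 1.87-fold lower there (limma adjusted p = 0.511). Leaving out mixture array 39 gave 10 probes past the threshold, and leaving out control array 5 gave 1. Direct comparisons between exposures gave 0 of 12955 liver probes for high against low PFOS and 0 for the mixture against high PFOS in limma, with 609 and 547 at an unadjusted p under 0.05 and 648 expected.

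Blood of fish at low PFOS had a median log2 change of 0.48 over 12895 probes against control, at 1.80 for the dimmest 20% of probes and -0.35 for the brightest 20%, and 3121 probes were higher and 576 lower at an unadjusted p under 0.05. Past the threshold in limma, 2 probes rose and 0 fell. Probe UF_Ppr_AF_116689 (contig gi_73491920___1_nr0nt1, sequence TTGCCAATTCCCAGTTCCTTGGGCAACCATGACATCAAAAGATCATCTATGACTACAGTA) was well above background on all 4 low PFOS arrays and on 0 of 4 controls, and rose at least 13.3-fold (limma adjusted p = 0.0395). Probe UF_Ppr_AF_112117 (contig FJU.2429.C1___1_nrnt, sequence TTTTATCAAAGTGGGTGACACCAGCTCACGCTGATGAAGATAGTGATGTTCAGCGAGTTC) rose at least 3.42-fold (limma adjusted p = 0.0489). UF_Ppr_AF_112117 was well above background on 0 of 4 controls. Its bound is no larger than the median change of the dimmest 20% of probes, but that median was taken on values as read. As read, its own log2 difference was 3.53 ± 0.52 (SE), with the controls at background. Whether its rise exceeds the shift of dim probes is therefore not settled. In liver, UF_Ppr_AF_116689 had a log2 difference of 3.14 ± 0.87 (SE) at low PFOS, with a limma adjusted p of 0.406. The difference between tissues did not pass for that probe (limma adjusted p = 0.332).

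Lower signal without passing the threshold at low PFOS was found in blood for UF_Ppr_AF_112246 (contig FJU.368.C2___1_nrnt, sequence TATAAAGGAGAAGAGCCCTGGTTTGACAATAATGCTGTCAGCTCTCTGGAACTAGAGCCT), at 0.67 ± 0.29 (SD, n = 4) against 3.51 ± 0.32 (SD, n = 4) in control, a log2 difference of -2.84 ± 0.47 (SE; limma adjusted p = 0.0641). UF_Ppr_AF_105278 (contig FJU.1362.C3___1rc_nrnt) had -2.04 ± 0.34 (SE; limma adjusted p = 0.0641). The log2 range between the 25th and 75th percentile of signal was 4.69 ± 1.60 (SD, n = 4) in low PFOS arrays and 6.52 ± 0.45 (SD, n = 4) in controls (exact permutation test, two-sided p = 0.0286, 70 assignments). Without low PFOS array 2, 0 of 12522 probes that still met the filter passed in limma, with 2450 at an unadjusted p under 0.05, and removal of other single arrays gave 0 to 805. Quantile normalization, normexp, the value table and the removal of 3 doubted blood arrays each gave 0 probes, while all 30 arrays gave 2426. With slide as a fixed block neither of the 2 probes passed (limma adjusted p = 0.104 for both).

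**Figure D2:**
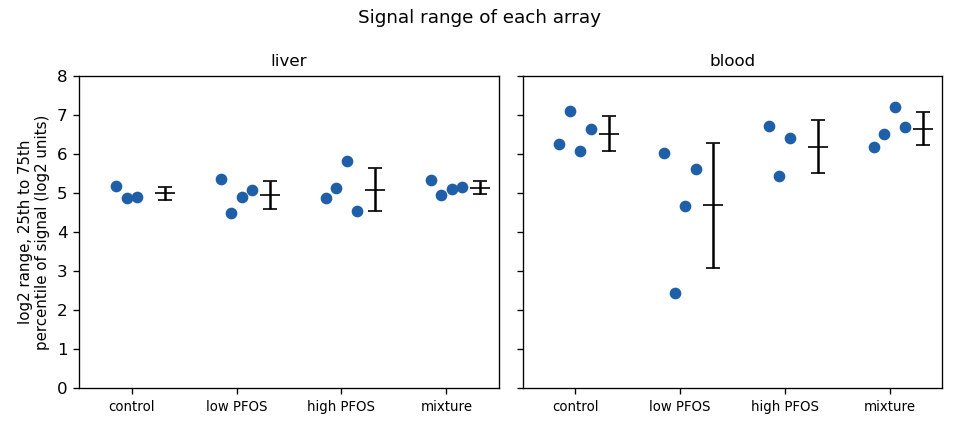
Log2 range between the 25th and 75th percentile of processed signal on each array (vertical axis, log2 units) by tissue and exposure (horizontal axis). Points are arrays and bars give the mean and SD. The 4 blood low PFOS arrays lie between 2.45 and 6.03, below the 4 blood controls at 6.08 to 7.10.

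At high PFOS in blood, 1 of 12895 probes passed in limma, and 385 had an unadjusted p under 0.05 where 645 are expected. That probe, UF_Ppr_AF_108509 (contig FJU.8562.C2___1_nr0nt1, sequence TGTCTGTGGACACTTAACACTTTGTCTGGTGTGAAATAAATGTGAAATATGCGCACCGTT), was well above background on all 3 high PFOS arrays, with processed signals of 110 to 343 intensity units, and on 0 of the other 12 blood arrays, where its signal reached 16.4 at most. It rose at least 16.5-fold against control (limma adjusted p = 0.00121). On each of 3 slides the high PFOS array lay above the highest other blood array, by 6.04, 5.63 and 4.97 log2 units as read, the other arrays being at background. That direction followed from the separation over all blood arrays. With only the 2 groups in the fit its adjusted p was 0.0528, and with each high PFOS array left out and no filter on dim probes it was 0.0265, 0.0246 and 0.00155.

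Other blood probes at high PFOS did not pass in limma. UF_Ppr_AF_115071 (contig FJU.6670.C2___1_nrnt) had a log2 difference of 1.81 ± 0.40 (SE), UF_Ppr_AF_112246 had -2.14 ± 0.51 (SE) and UF_Ppr_AF_103527 (contig FJU.5268.C1___1rc_nrnt-1) had -2.87 ± 0.74 (SE), each with an adjusted p of 1.00. For the mixture in blood, 0 of 12895 probes passed in limma, with 550 at an unadjusted p under 0.05. UF_Ppr_AF_115071 had 2.03 ± 0.37 (SE) and UF_Ppr_AF_115768 (contig FJU.9303.C3___1_nrnt), well above background on 1 of 4 control arrays, had 3.35 ± 0.65 (SE), both with an adjusted p of 0.744. UF_Ppr_AF_105343 (contig FJU.2484.C1___1_nrnt) had -3.32 ± 0.67 (SE; limma adjusted p = 0.744), and UF_Ppr_AF_101592 (contig FJU_SB_30.28.C1___1_nr1nt0), well above background on 1 of 4 mixture arrays, had -8.24 ± 1.92 (SE; limma adjusted p = 0.999). The size of the latter depends on values at background. UF_Ppr_AF_101592 stood at 1.36 ± 0.68 (SD, n = 4) in blood control. It varied widely elsewhere, at -1.42 ± 4.84 (SD, n = 3) in blood high PFOS and 1.77 ± 4.86 (SD, n = 3) in liver control.

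**Figure D3:**
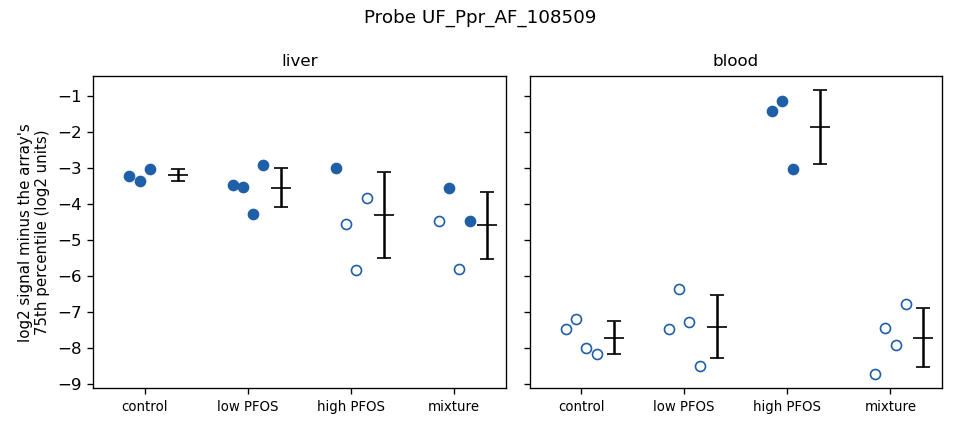
Log2 signal of probe UF_Ppr_AF_108509 relative to the 75th percentile of the array (vertical axis, log2 units) in liver and blood of the 4 exposure groups (horizontal axis). Each point is 1 array, filled where the probe was well above background and open where it was not, and bars give the mean and SD. In blood the 3 high PFOS arrays lie between -3.03 and -1.14 and every other array lies at or below -6.37.

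Between the PFOS concentrations in blood, 10 of 12895 probes differed in limma, with 1 higher and 9 lower at high PFOS. UF_Ppr_AF_108509 was at least 14.8-fold higher at high than at low PFOS (adjusted p = 0.00234). UF_Ppr_AF_112895 (contig FJU_SB_30.143.C1___1_nr2nt, sequence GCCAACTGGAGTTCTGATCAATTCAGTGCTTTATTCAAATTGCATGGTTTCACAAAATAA) was at least 35.9-fold lower at high PFOS (adjusted p = 0.0444), at least 17.1-fold without low PFOS array 4 and at least 66.2-fold without low PFOS array 3, and was not well above background on any high PFOS array. The median change over all probes was -0.33 log2 units, with 145 probes higher and 1630 lower at an unadjusted p under 0.05. The 9 lower probes lie in the direction of this shift of the low PFOS arrays and were not separated from it. UF_Ppr_AF_112895 had 3 unflagged low PFOS values and also varied in blood control, at -4.33 ± 2.17 (SD, n = 4). With slide as a fixed block 1 probe passed, and without low PFOS array 2 it was also 1, in both cases UF_Ppr_AF_108509 and not UF_Ppr_AF_112895; with only the 2 groups in the fit 0 passed.

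The mixture against high PFOS in blood gave 1 of 12895 probes in limma. This was UF_Ppr_AF_108509, at least 15.1-fold lower with the mixture (adjusted p = 0.0012). No other probe passed, and 311 had an unadjusted p under 0.05. With only the 2 groups in the fit the limma adjusted p of UF_Ppr_AF_108509 was 0.0712.

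Whether an exposure acted differently in blood and liver was tested as an interaction. For high PFOS 1 of 13855 probes passed in limma. This was UF_Ppr_AF_108509, with a difference between the log2 changes of at least 4.77 by the rule for dim groups (limma adjusted p = 0.000273). This result and those of the probe within blood rest on the same 3 high PFOS blood arrays, so they are not separate findings. The liver level of UF_Ppr_AF_108509 was -3.20 ± 0.17 (SD, n = 3) in control and -4.30 ± 1.19 (SD, n = 4) at high PFOS. At high PFOS 1 of the 4 liver arrays was well above background, so that level is uncertain. For low PFOS 0 probes passed (2545 at an unadjusted p under 0.05, 693 expected), and for the mixture 0 passed (572 at an unadjusted p under 0.05). The median difference between tissues in the low PFOS change was 0.52 log2 units.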

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

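The tests of slide, liver RNA and on-off variation on UF_Ppr_AF_108509, and both tests on the low PFOS shift in blood, were chosen after the result was seen. The effect of high PFOS differed between tissues at 1 probe by its interaction test, UF_Ppr_AF_108509 (log2 difference of at least 4.77). A slide effect is argued against by the layout, since each of the 3 slides with a high PFOS blood array also held other blood arrays, which were at background. The gap to the highest of these within a slide was at least 4.97 log2 units as read, their own level being uncertain. It followed from the separation for which the probe was singled out, so its size adds no support. Light from adjoining spots is argued against by their mean change of 0.31 log2 units against a rise of at least 16.5-fold at the probe, and liver RNA in the blood by the 208 liver-enriched probes, which differed by 0.05 log2 units from control; the probe's mean level was 2.08 log2 units above that in liver (10 of 15 arrays well above background), though the highest liver array (-2.92) lay above the lowest high PFOS blood array (-3.03). On-off variation between fish stays open: of 11 probes on in 3 blood arrays alone, 0.0242 would match the high PFOS arrays by chance, but the 1 that did is the probe singled out for that pattern. A response to 25 µg/L PFOS is a hypothesis; fish sharing an aquarium, a transcript variant under the probe and cross-hybridization were not tested, and 7 of the 35 splits of the high PFOS and control arrays gave 1 probe or more (highest other 1), so as a count the result could arise by chance.

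Several blood arrays stood apart in groups of 4. Spots flagged by the scanner software numbered 1836 on mixture array 4 (0 to 22 on the others of its group), 1255 on low PFOS array 2 (8 to 24) and 112 on control array 2 (0 to 15). Low PFOS array 2 had a Spearman correlation of 0.792 with the median blood profile (0.953 to 0.972), and low PFOS array 3 had 96 saturated spots (131 to 133). The shift of low PFOS blood is not due to array 2 alone, since without it the median change was still 0.35 log2 units, with 2179 probes higher and 334 lower at an unadjusted p under 0.05 of the 12892 that met the filter on all blood arrays. A narrower signal range goes with this shift, since every low PFOS array had a narrower range than every control. The dimmest probes (lowest 20%) changed by 2.15 log2 units more than the brightest 20% (1.25 without array 2). That difference largely restates the narrower range, so it is no separate support. Probes were also ranked partly on the control arrays, which by itself favours a rise of dim probes. The range remains a candidate explanation. A change of the blood itself with exposure was not tested and stays open.

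Liver mixture array 39 had a 75th percentile signal of 618 intensity units, against 351 to 388 on the others of its group. Among the named probes past the threshold, single arrays stood apart for UF_Ppr_AF_116689 on blood mixture array 4 (-7.00), UF_Ppr_AF_112117 on blood low PFOS array 2 (-3.09), UF_Ppr_AF_112895 on blood control array 2 (-7.57) and UF_Ppr_AF_118877 on blood control array 2 (5.07). In all, 10 checks stood out of at most 84, since groups with a flagged value of a probe were skipped. Chance gives about 1 in 20 for independent, normally distributed values, which counts of spots and measures of the same array need not be.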

How the results depend on the processing

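Array weights, the removal of 3 doubted blood arrays (low PFOS 2, mixture 4, control 2), the identities of the value table and the contrast of all liver exposures with control were chosen after seeing the data. No named probe changed direction in any of 835 values under an alternative: 750 stayed on the same side of the threshold, 56 no longer passed it and 29 newly passed it, whatever the change in size. Apart from the tissue difference, every named probe had no overlap between the groups compared. Leaving out single arrays could therefore not reverse it, and its kept direction there is no support. UF_Ppr_AF_116689 in blood at low PFOS passed under 11 of 27 alternatives, UF_Ppr_AF_112117 under 9 of 27, UF_Ppr_AF_112895 for high against low PFOS under 8 of 27 (log2 differences of -8.07 to -2.87, adjusted p up to 0.695 in limma) and UF_Ppr_AF_108509 at high PFOS under 23 of 24. With normexp, whose offset of 50 shrinks changes of dim probes, the log2 differences of UF_Ppr_AF_116689, UF_Ppr_AF_112117 and UF_Ppr_AF_108509 were 1.24, 0.22 and 2.11, so the folds given for them hold for the processed signal. The value table was not run for fits of both tissues, and UF_Ppr_AF_108509 drops out of the tested probes in fits of blood alone when a high PFOS array is left out, and in all fits when every array must be above background. For dim liver probes that did not pass, sizes also depended on the setting. Under the alternatives the log2 difference of UF_Ppr_AF_105283 came down to -1.186 at low PFOS and -1.079 at high PFOS. With the mixture it came down to -1.127 for UF_Ppr_AF_100743 and -0.1878 for UF_Ppr_AF_109691, the latter below the bound given for it. Unless stated, the cause of a change was not tested.

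In liver, low PFOS against control (0 probes) gave 5 with normexp, 3 with the value table, 2 with every array above background, 7 with all 30 arrays and 41 with array weights; high PFOS gave 2 with normexp and 2 with all 30 arrays. Leaving out single arrays gave 0 to 1 for low PFOS (1 without high PFOS 31, high PFOS 27, low PFOS 13 or low PFOS 11), 0 to 1 for high PFOS (1 without mixture 39) and 0 to 10 for the mixture (10 without mixture 39, 1 without control 5). The mixture, high against low PFOS and the mixture against high PFOS stayed at 0 under all other settings. All exposures against control (1) gave 4 with normexp, 0 with quantile normalization, 0 without a filter, 5 with every array above background, 0 with slide fixed, 4 with all 30 arrays (without UF_Ppr_AF_103929), 30 with array weights, and 0 to 28 with single arrays left out (28 without mixture 39, 1 without low PFOS 11, 1 other probe without control 5 or low PFOS 13, and 0 without any other array).

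In blood, low PFOS against control (2) gave 0 with normexp, quantile normalization, the value table, no filter, every array above background, the doubted arrays removed or value table identities, 1 with slide fixed (neither of the 2), 2426 with all 30 arrays, 14 with only 2 groups and 479 with array weights. High PFOS (1) gave 3 with the value table, 2 with slide fixed, array weights or value table identities, and 0 with every array above background or only 2 groups. The mixture (0) gave 1 with value table identities. High against low PFOS (10) gave 1 with normexp, quantile normalization or slide fixed, 2 with the value table, 5 without a filter, 0 with every array above background or only 2 groups, 64 with all 30 arrays, 1782 with array weights, 18 with the doubted arrays removed and 23 with value table identities. The mixture against high PFOS (1) gave 0 with every array above background, 2 with array weights and, with only 2 groups, 1 other than UF_Ppr_AF_108509. Leaving out single arrays gave 0 to 805 for low PFOS: 805 without high PFOS 2, 8 without low PFOS 1, 5 without control 3, 3 without low PFOS 3 (neither of the 2) or low PFOS 4, 1 without high PFOS 1 or control 1 (with control 1 left out, neither of the 2), and 0 without low PFOS 2, control 2, control 4, high PFOS 3, mixture 1, mixture 2 or mixture 3. It gave 0 to 2 for high PFOS (0 without any high PFOS array, 2 without control 1 or control 2), 0 to 1 for the mixture (1 without control 1 or control 2) and 0 to 1 for the mixture against high PFOS (0 without any high PFOS array). High against low PFOS ranged from 0 to 21: 21 without low PFOS 3, 19 without control 2, 7 without high PFOS 2 (1 of them among the 10), 6 without low PFOS 1, 3 without mixture 4, low PFOS 4, control 3 or control 4, 2 without mixture 1, 1 without mixture 2, mixture 3, low PFOS 2 or control 1, and 0 without high PFOS 1 or high PFOS 3.

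With the replicate number as a block, low PFOS gave 4 and high against low PFOS gave 3, and no other blood count moved; the numbers do not pair the arrays (6 of 21 pairs over 0.1, and 5 of 15 arrays correlated best with their own number).

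For tissue differences, low PFOS (0) gave 2 with every array above background and 110 with array weights; high PFOS (1) gave 0 with every array above background, and 3 with array weights, the doubted arrays removed or value table identities; the mixture (0) gave 1 with the doubted arrays removed or value table identities. With single blood arrays left out, low PFOS gave 0 to 158 (158 without high PFOS 2, 29 without low PFOS 1, 3 without low PFOS 4 or control 1), high PFOS 1 to 3 (3 without control 2, 2 without control 1) and the mixture 0 to 1 (1 without control 1 or control 2). Liver against blood controls (6731) gave 2812 with every array above background, where fewer probes are tested, and 5601 to 7159 with single arrays left out.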

Other observations

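The tissue-enriched probe sets were chosen after seeing the data. The simulation of shared controls was revised after its first result was seen, because the first form forced the simulated changes to correlate fully. A set of 64 probes at least 16-fold higher in blood than in liver on average, yet above background on every liver array, stood in liver at -0.72 ± 0.43 (SD, n = 3) in control, -1.05 ± 0.50 (SD, n = 4) at low PFOS, -1.07 ± 0.30 (SD, n = 4) at high PFOS and -1.38 ± 0.18 (SD, n = 4) with the mixture, in log2 units. The mixture differed from control by -0.67 (exact permutation test, two-sided p = 0.0571, 35 assignments; 0.343 adjusted over 6 tests). With camera at a preset correlation between genes its adjusted p was 2.19e-08, and 0.356 with an estimated correlation. A set of 208 liver-enriched probes differed in blood by 0.25 at low PFOS, 0.05 at high PFOS and 0.24 with the mixture (exact permutation p = 0.2, 0.714 and 0.2).

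Liver log2 changes at low and high PFOS correlated across 12837 probes at 0.64, low PFOS and mixture at 0.66, and high PFOS and mixture at 0.62, where probes are not independent replicates. Unchanged simulated groups sharing their controls gave mean correlations of 0.54, 0.55 and 0.54. The covariances were 0.296, 0.292 and 0.287 against simulated means of 0.222, 0.222 and 0.213, with 26, 25 and 23 of 100 simulations as large, and each lay below the highest simulated covariance (0.720, 0.591 and 0.593), by the most for low and high PFOS (-0.42). Each simulated array was the residual of a randomly drawn array with a random sign, and the same array could be drawn for several groups. Such repeats widen the simulated values, so the counts of simulations as large cannot decide the question. Sharing controls by itself gave a positive correlation, as the simulated means show. Whether the likeness of the liver exposures goes beyond the spread of the 3 shared controls stays open. These were too few to give each exposure controls of its own. In blood the correlations were 0.49, 0.36 and 0.56, against simulated means of 0.41, 0.48 and 0.43. They were 0.20, 0.08 and 0.09 with the blood controls divided evenly between the exposures of a pair. Fewer controls add noise, which lowers a correlation by itself. The covariances were 0.391, 0.267 and 0.253 with shared controls and 0.194, 0.071 and 0.057 with divided controls. With all liver exposures set against control 1 probe passed, UF_Ppr_AF_103929 (log2 difference 1.99 ± 0.27, SE; limma adjusted p = 0.0445), and 16 of 100 splits gave as many (highest other 8).

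Other splits of the same arrays bear on chance only as far as arrays are independent, which fish sharing an aquarium would not be. Liver against blood controls (6731, highest other 4559) had the smallest share possible (1 of 35, the real split). Since liver and blood came from the same fish, that condition is not known to hold for it. Blood low PFOS against control (2 probes, highest other 1), its 3697 probes at an unadjusted p under 0.05 (highest other 2521) and blood high against low PFOS (10 probes, highest other 5) also had 1 of 35, but without low PFOS array 2 these counts were 0, 2450 and 1, so no exclusion of chance is read from them. Chance cannot be excluded for the mixture against high PFOS in blood (1 probe, 5 of 35, highest other 3) or the tissue difference in the high PFOS effect (1 probe, 10 of 100, highest other 3). The liver counts of 0 were matched by 35 of 35 splits, as any count of 0 must be, so the match does not bear on chance. Highest other counts were 2 for low PFOS, 13 for high PFOS, 29 for the mixture, 1 for high against low PFOS and 5 for the mixture against high PFOS. The splits with 13 and 29 probes point to a structure among these arrays whose source was not tested; that with 29 put mixture array 39 beside control arrays 3 and 4. For the same reason the blood mixture count of 0 was matched by 35 of 35 (highest other 1). The tissue differences of 0 for low PFOS and the mixture were likewise matched by 100 of 100 (highest other 3 and 2). As any count of 0 must be matched, these do not bear on chance.

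Counts at an unadjusted p under 0.05 were matched or exceeded by 7 of 35 splits for liver low PFOS (960, highest other 1301), 10 for liver high PFOS (892, highest other 1541), 8 for liver mixture (829, highest other 1818), 15 for blood high PFOS (385, highest other 1377) and 10 for blood mixture (550, highest other 1401), so chance cannot be excluded for these.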
